A study of Homo sapiens with 70 samples.

How the data were processed

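RNA was sequenced from sotorasib-resistant MIA PaCa-2 cells that carried doxycycline-inducible dCas9-KRAB and 1 of 3 guide RNAs. The guides were sgZBTB11-1 and sgZBTB11-2, which target ZBTB11, and sgNS, a control. Cells received DMSO or doxycycline (DOX) and were collected at 5 hr and at days 1, 3 and 5. Groups were taken from the labels alone, and 70 libraries fell into 24 groups of 2 or 3. Nothing in the labels says that libraries of a group came from separate cultures, so p-values here measure only the spread between these libraries, which may be technical.

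The authors deposited a table of expected counts per gene, which are estimates and need not be whole numbers, and a table of TPM (transcripts-per-million). RSEM and the genome build GRCh38.p14 are named in the submitters' processing notes. The aligner, the annotation version, the RSEM version and the strand setting are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart, which concerns ZBTB11 with ZBTB11-AS1 and CENPT with THAP11. Expected counts split reads between near-identical copies by estimation, so values of pseudogenes, readthrough transcripts and close paralogs are uncertain. Both tables held 78932 genes, of which 33163 had no count in any library, and 0 columns belonged to other samples. Expected counts were rounded to whole numbers, and 5.13% of all values differed from the nearest whole number before rounding, with no tolerance.

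Coordinates are those of the RefSeq gene table of the same build. Total counts per library were 12068833 to 20627648. Over the 68 pairs of libraries within groups, a chi-square of the counts per degree of freedom, over genes with at least 20 counts in the pair, ranged from 1.33 to 4.93 with a median of 1.63. Identical pairs numbered 0, so every library was counted once.

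Tests used edgeR 4.0.16 in R 4.3.3, with filterByExpr by group, TMM scaling and robust quasi-likelihood F tests. All libraries of a time point entered 1 fit with a mean per group and no block, because nothing in the labels ties a replicate number to a shared culture or day. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and the threshold was an adjusted p of 0.05. The net change of a gene was the mean of the DOX minus DMSO log2 changes of the 2 ZBTB11 guides, minus the DOX minus DMSO log2 change of sgNS. DOX was also compared with DMSO within each guide, the 2 ZBTB11 guides were compared with each other and, with DMSO alone, with sgNS, and net changes at neighbouring time points were compared in 1 fit of all 70 libraries. The DMSO libraries of the 2 ZBTB11 guides are separate, so agreement between these guides shares no library, whereas net changes of both share the sgNS libraries. Values in CPM (counts-per-million) are TMM-scaled.

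Named genes followed a rule. At each time these were the 10 largest increases and the 10 largest decreases of the net test among genes past the threshold, with a mean CPM of at least 5 and a DOX change of the same sign as the net change in both ZBTB11 guides. ZBTB11, its neighbouring genes, up to 5 genes with the largest DOX change in sgNS per time, and up to 4 members of each described list with the largest net change were added. Members were taken from those past the threshold, or from all tested members where none passed. Other genes are said to have been chosen after their values were seen. The genes changed by both ZBTB11 guides and net of sgNS, which pass the threshold in all 3 tests in 1 direction, are a count that was defined after the data were seen.

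Gene lists numbered 40 and held 1102 symbols, of which 0 were missing from the table. They covered mitochondrial complexes and translation, ribosomes, metabolism, stress responses, signalling, cell cycle, genes near ZBTB11 and markers of other cell types. The 37 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a time point, and again with the correlation estimated from the data. Groups, tests, lists, the rule for named genes and all alternatives not said otherwise were fixed before the data were examined.

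The tests were run on simulated data drawn from the real library sizes and means, with 200 genes changed. The changed genes were taken from those with a mean CPM of at least 5. Each gene was drawn independently, so the false calls do not reflect effects that many genes of a library share. For the net test at day 3 over 16437 genes, 40% of 50 genes changed by 0.25 on the log2 scale were called, 84% at 0.5, 96% at 1 and 100% at 2, with 5 false calls.

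The alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, a block by replicate number, 1 fit of all libraries, limma 3.58.1 on log2 of the deposited TPM plus a pseudocount of 1 for genes with a TPM of at least 1 in 3 libraries, and leaving out each library in turn. Fold changes on the log2(TPM + 1) scale understate the change of low genes. The alternatives chosen after seeing the data were a smooth trend with transcript length and GC content removed per library by splines with 4 degrees of freedom, and the mean change of both ZBTB11 guides without the sgNS term. DESeq2 without its independent filtering was added later too, because that filter left some named genes with no adjusted p. Effective transcript length came from the ratio of the deposited counts to the deposited TPM, and GC content from reference transcripts read with Biostrings 2.70.1. At least 97% of the genes with a mean CPM of 5 or more had both values. Statmod 1.5.0, data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9 were also used. Under TMM and RLE scaling the median DOX or net change of all tested genes was at most 0.016 from 0 on the log2 scale. On the TPM scale the medians of the net change were -0.13 at 5 hr, -0.01 at day 1, 0.07 at day 3 and 0.19 at day 5, so changes of gene lists are given relative to the median gene.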

Results

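MIA PaCa-2 is an established line of pancreatic ductal adenocarcinoma, used here in a form resistant to the drug sotorasib. The cells carried dCas9-KRAB, a catalytically dead Cas9 fused to a repressor domain, under a doxycycline-inducible promoter. A guide RNA directs this protein to a promoter, where it lowers transcription. Poly(A) RNA was sequenced from cells with sgZBTB11-1, sgZBTB11-2 or the control guide sgNS, given DMSO or doxycycline (DOX), at 5 hr and at days 1, 3 and 5. The 70 libraries made up 24 groups of 3 libraries, except sgNS with DMSO at day 1 and sgZBTB11-1 with DMSO at day 5, which had 2. Each library held 12068833 to 20627648 counts. Transcripts encoded by mitochondrial DNA took 13.1% ± 0.84 of counts at 5 hr (SD, n = 18), 11% ± 1 at day 1 (n = 17), 19.8% ± 1.6 at day 3 (n = 18) and 30.7% ± 2.5 at day 5 (n = 17).

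The first question was whether DOX lowered ZBTB11, a zinc finger transcription factor (ENSG00000066422.7, chromosome 3, 101648889 to 101677132), in the cells that carried guides against it. In sgZBTB11-2 cells its level was 52.1 ± 1.3 CPM (counts-per-million) with DMSO and 46.2 ± 0.57 with DOX at 5 hr (SD, n = 3 each). It was 46.8 ± 4.2 and 31.1 ± 0.7 at day 1, 49.3 ± 1.5 and 28.6 ± 0.35 at day 3, and 49.1 ± 1.3 and 26.3 ± 0.47 at day 5. In sgZBTB11-1 cells it was 52.8 ± 2.5 and 52.8 ± 0.61 at 5 hr, 50.1 ± 2.8 and 41.4 ± 1.2 at day 1, 49.8 ± 0.72 and 36.3 ± 1.9 at day 3, and 45.2 ± 2.3 (n = 2) and 33.8 ± 1.8 at day 5. In sgNS cells it was 48.3 ± 1.6 and 54.3 ± 3 at 5 hr, 53.4 (n = 2) and 49.3 ± 1.3 at day 1, 59.1 ± 4.6 and 56.8 ± 3.7 at day 3, and 52.7 ± 4.2 and 47.5 ± 3.1 at day 5. Every DOX library was below every DMSO library in sgZBTB11-2 at all 4 times, in sgZBTB11-1 at days 1, 3 and 5, and in sgNS at day 1. Chance separates DOX from DMSO libraries, in either direction, in 10% of splits of 3 against 3, and in 20% of splits of 3 against 2 as for sgNS at day 1 and sgZBTB11-1 at day 5.

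**Figure D1:**
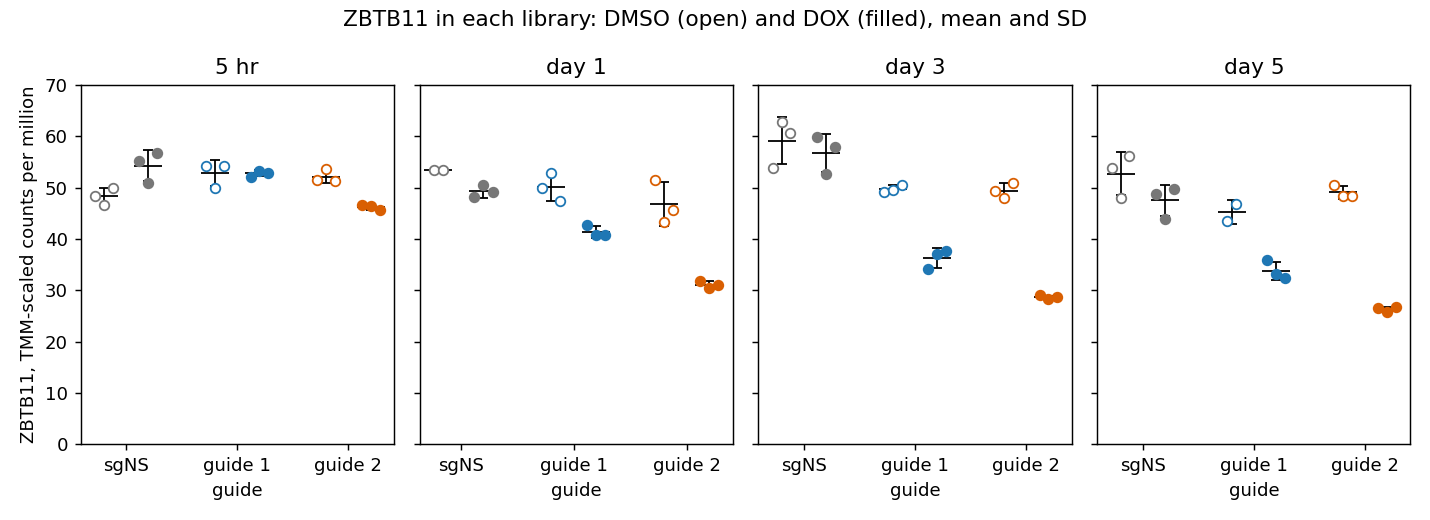
ZBTB11 in TMM-scaled counts-per-million (vertical axis) in each library, by guide (horizontal axis) and time (panels). Open points are DMSO and filled points DOX, and the bar is the mean with its SD. At day 5 the means with DOX are 33.8 in sgZBTB11-1, 26.3 in sgZBTB11-2 and 47.5 in sgNS.

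In edgeR's quasi-likelihood test the log2 change of ZBTB11 with DOX in sgZBTB11-2 was -0.17 at 5 hr (adjusted p = 0.0072), -0.59 at day 1 (1.3e-09), -0.79 at day 3 (6.1e-13) and -0.9 at day 5 (4.9e-17). In sgZBTB11-1 it was 0 (0.96), -0.28 (0.00077), -0.45 (2.8e-06) and -0.42 (6.5e-05). The deepest mean fall was thus -46.4%, with sgZBTB11-2 at day 5. In sgNS ZBTB11 rose by 0.17 at 5 hr (0.003), was at -0.11 at day 1 (0.4) and -0.06 at day 3 (0.71), and fell by 0.15 at day 5 (0.032). Net of sgNS its change was -0.26 at 5 hr (SE 0.057, 0.00045), -0.32 at day 1 (SE 0.07, 0.055), -0.56 at day 3 (SE 0.065, 8.3e-07) and -0.5 at day 5 (SE 0.068, 6e-08). The fall was larger with sgZBTB11-2 than with sgZBTB11-1 by the test of the difference at 5 hr (-0.17, adjusted p = 0.04) and day 5 (-0.48, 0.00026), and not past the threshold at day 1 (-0.32, 0.1) or day 3 (-0.33, 0.27). The net change at day 1, which did not pass, ranged from -0.36 to -0.28 over the alternatives on counts, with adjusted p up to 0.35, and was -0.29 (0.71) in limma on TPM. It passed without sgZBTB11-1 DMSO replicate 3 (0.038) or sgZBTB11-2 DMSO replicate 2 (0.005), in 1 fit of all 70 libraries (0.033), with no filter on low counts (0.0032) and with the length and GC trend removed (-0.36, 0.00068). With DMSO alone ZBTB11 in sgZBTB11-1 cells was above sgNS at 5 hr (0.13, 0.023) and below it at day 3 (-0.25, 0.00076) and day 5 (-0.23, 0.0023), but not past the threshold at day 1 (-0.09, 0.29). In sgZBTB11-2 cells it was below sgNS at day 1 (-0.19, 0.033) and day 3 (-0.26, 0.0013), but not past the threshold at 5 hr (0.11, 0.063) or day 5 (-0.11, 0.15). On the TPM scale in limma the net change was -0.43 at day 3 (0.089) and -0.23 at day 5 (0.069), and the call in sgZBTB11-1 was lost at all 3 days (0.39, 0.053 and 0.22). With a length and GC trend removed, the net change at 5 hr was -0.04 (0.71). The guides differed at 5 hr for 5478 of 15623 genes, with a median size of 0.37, so the difference of ZBTB11 there was not particular to it.

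DOX also changed genes in sgNS cells, where ZBTB11 is not targeted. CENPT, a kinetochore protein (ENSG00000102901.13, chromosome 16, 67828157 to 67847693), had the smallest adjusted p of the sgNS test at day 1. There it went from 94.8 ± 5.8 (n = 2) to 250 ± 13 CPM in sgNS, from 93.6 ± 3.4 to 316 ± 6.6 in sgZBTB11-1 and from 103 ± 4.7 to 306 ± 5.4 in sgZBTB11-2 (SD, n = 3). Its log2 change in sgNS was 0.87 at 5 hr, 1.4 at day 1, 0.61 at day 3 and 0.38 at day 5 (adjusted p = 1.7e-19, 2.1e-22, 2.7e-09 and 2.7e-13). THAP11, a zinc finger transcription factor whose gene lies within the span of CENPT (67842320 to 67844195), fell at day 1 in sgNS (-0.92), sgZBTB11-1 (-1.15) and sgZBTB11-2 (-0.79). Reads of this overlapping pair are uncertain without the strand setting. SLC25A36, a mitochondrial carrier of pyrimidine nucleotides, rose by 0.63, 0.71 and 0.78 in the same order, FBXL19-AS1 by 0.86, 1.18 and 1.13, and UBXN8 by 0.8, 0.86 and 0.93. With ENSG00000233461 (0.91) these genes are the largest changes in sgNS at day 1 among genes with a mean CPM of at least 5, except SLC25A36, which was chosen after its values were seen, as were the other times of CENPT. DOX changed 144 genes past the threshold in all 3 guides at day 1, of which 31 were higher and 113 lower.

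Counts of genes changed by DOX within a guide are given for 5 hr and days 1, 3 and 5 in that order. In sgNS they were 6395 (3260 higher and 3135 lower), 356 (91 and 265), 146 (67 and 79) and 2915 (1491 and 1424). In sgZBTB11-1 they were 5130 (2717 and 2413), 787 (267 and 520), 122 (32 and 90) and 191 (61 and 130). In sgZBTB11-2 they were 2659 (1304 and 1355), 1282 (558 and 724), 195 (46 and 149) and 1513 (505 and 1008). Single libraries moved several of these counts by over 1.5 times. For sgNS at day 1 the count was 168 and 103 without DMSO replicates 1 and 2, and 189 and 237 without DOX replicates 1 and 2. At day 3 it was 278, 40 and 57 without DMSO replicates 1, 2 and 3, and 71, 44 and 72 without DOX replicates 1, 2 and 3. For sgZBTB11-1 at day 1 it was 475 and 420 without DMSO replicates 1 and 3, and 443, 458 and 479 without DOX replicates 1, 2 and 3. At day 3 it was 57 and 44 without DMSO replicates 1 and 2, and 46 without DOX replicate 3. At day 5 it was 27 and 65 without DMSO replicates 1 and 2, and 74 and 85 without DOX replicates 1 and 3. For sgZBTB11-2 at day 1 it was 1965, 680 and 775 without DMSO replicates 1, 2 and 3, and 599 without DOX replicate 3, and at day 3 it was 116 and 109 without DMSO replicates 2 and 3, and 128 without DOX replicate 3.

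Decreases net of sgNS at day 3 included COQ3, AGK, MRPL48 and C17orf75. COQ3, a methyltransferase of coenzyme Q synthesis, went from 15.3 ± 0.28 to 8.41 ± 0.47 CPM in sgZBTB11-2 (SD, n = 3), and its net log2 change was -0.74 (SE 0.1, adjusted p = 2.2e-05). AGK, an acylglycerol kinase of the mitochondrial TIM22 import complex, fell by 0.49 (SE 0.066, 2.2e-05), and MRPL48, a protein of the large mitochondrial ribosomal subunit, by 0.53 (SE 0.1, 0.0071). C17orf75, a partner of the WDR11 complex at the trans-Golgi, fell by 0.52 (SE 0.073, 3.5e-05). In sgNS the DOX changes of these 4 genes were 0.07, 0.09, 0.06 and 0.1, and each was below the DMSO mean in 6 of 6 DOX libraries of the ZBTB11 guides. The genes were picked for their fall in these same libraries, so the 6 of 6 adds no support. LINC00920 (-0.88) and PSD (-0.56) fell as well, and so did the pseudogene RPLP0P9 (-0.69), whose reads are uncertain.

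Increases net of sgNS at day 3 included EGR3, an immediate early transcription factor, at 0.8 (SE 0.1, adjusted p = 1e-05). Its log2 change was 0.51 in sgZBTB11-1, 0.22 in sgZBTB11-2 and -0.43 in sgNS. SLC25A24, a mitochondrial carrier of ATP-Mg and phosphate, was higher by 0.57 (SE 0.11, 0.0083), ITGAV, an integrin subunit, by 0.41 (SE 0.083, 0.0083), and NFKBIA, an inhibitor of NF-kB, by 0.26 (SE 0.049, 0.0046). SLC25A24 and ITGAV were at -0.5 and -0.35 in sgNS, and at 0.13 or below in the ZBTB11 guides. MEX3B (0.64), KIF3A (0.33), SPIDR (0.33), FTSJ3 (0.28), ANGEL2 (0.28) and MIDN (0.24) were the others. NR4A1, named for its DOX change in sgNS (-0.62), was higher by 0.67 net of sgNS.

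The net test called 82 of 16645 genes at day 3, 26 higher and 56 lower. The count depended on single libraries: it was 262, 31 and 29 without sgNS DMSO replicates 1, 2 and 3, 46, 41 and 29 without sgNS DOX replicates 1, 2 and 3, 51 without sgZBTB11-1 DMSO replicate 2, and 47 and 45 without sgZBTB11-2 DMSO replicates 2 and 3. MRPL48 lost its call without sgNS DMSO replicate 2 (adjusted p = 0.075) or sgNS DOX replicate 3 (0.072), NFKBIA without sgNS DMSO replicate 2 (0.069), ITGAV without sgNS DMSO replicate 2 (0.074), sgNS DMSO replicate 3 (0.08) or sgNS DOX replicate 3 (0.057), SLC25A24 without sgNS DMSO replicate 3 (0.072), without sgNS DOX replicate 3 (0.06) or in DESeq2 without independent filtering (0.061), and KIF3A without sgNS DMSO replicate 2 (0.1), sgNS DMSO replicate 3 (0.11) or sgNS DOX replicate 3 (0.085). COQ3, AGK, C17orf75 and EGR3 stayed past the threshold without any 1 library, while PSD, RPLP0P9, ANGEL2, MIDN, FTSJ3, MEX3B and SPIDR lost their calls in 11, 12, 11, 11, 12, 17 and 17 of the runs that changed a setting or left out a library. The count was 22 (15 higher and 7 lower) in limma on TPM, 195 (91 and 104) with no filter on low counts, 45 (14 and 31) in DESeq2 without independent filtering, and 420 (99 and 321) without the sgNS term.

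The gene lists at day 3 gave 11 calls of 37 in camera, 3 up and 8 down, on small shifts, and none was kept with an estimated correlation. Of 50 tested proteins of the large mitochondrial ribosomal subunit, 5 fell, 0 rose and 45 did not pass (10 fell adjusted over the list alone), with a median of -0.08 (adjusted p = 2.4e-10, and adjusted p = 0.12 with an estimated correlation). Of 79 cytosolic ribosomal proteins 4 fell, among them RPL34 (-0.25) and RPL26 (-0.21), and 75 did not pass (31 fell adjusted over the list alone; adjusted p = 3.1e-24, and 0.26 with an estimated correlation). Of 37 complex I subunits 1 fell, NDUFA12 (-0.26, SE 0.063, adjusted p = 0.043; list 4.3e-06, and 0.31 with an estimated correlation), also 1 adjusted over the list alone. Complex IV had 1 of 35 lower, COX7C at -0.2 (4.3e-06, 0.19 with an estimated correlation; 6 adjusted over the list alone), and ATP synthase 1 of 20, the assembly factor ATPAF1 at -0.28 (9.2e-10, 0.19 with an estimated correlation; 8 adjusted over the list alone). Median DOX changes of complex IV were 0 in sgZBTB11-1, -0.03 in sgZBTB11-2 and 0.07 in sgNS, and camera did not call it without the sgNS term (adjusted p = 0.37).

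None of the 13 mRNAs encoded by mitochondrial DNA passed at day 3 (8 fell adjusted over the list alone), and their list was called down with a median of -0.1 (adjusted p = 4.3e-06, and 0.19 with an estimated correlation). Their median DOX changes were 0.01 in sgZBTB11-1, 0.14 in sgZBTB11-2 and 0.18 in sgNS. The share of mitochondrially encoded counts went from 18.4% to 19.9% in sgNS and from 17.9% to 19.1% in sgZBTB11-2, and was 21.8% with both treatments in sgZBTB11-1. The small mitochondrial ribosomal subunit (0 of 32, also adjusted over the list alone, with 8 lower at an unadjusted p under 0.05; 0.00037, and 0.17 with an estimated correlation) and mitochondrial import (0 of 38 by both adjustments, 1 higher and 5 lower unadjusted; 0.028, and 0.33 with an estimated correlation) were also called down. On the TPM scale, where the median gene was at 0.07, these last 2 lists stood at 0.02 and 0.05, and below the median gene. RAS-MAPK output genes were called up with 0 of 24 past the threshold (4 higher and 2 lower adjusted over the list alone; 0.014, and 0.26 with an estimated correlation). G2/M genes (0 of 40 by both adjustments, 3 higher and 1 lower unadjusted; 0.028, and 0.27 with an estimated correlation) and apoptosis regulators (0 of 27 by both adjustments, 4 higher unadjusted; 0.049, and 0.17 with an estimated correlation) were called up as well. Median DOX changes of RAS-MAPK output were 0.03 in sgZBTB11-1, -0.02 in sgZBTB11-2 and -0.07 in sgNS. In the same order they were 0.04, -0.01 and -0.02 for G2/M genes and 0.02, -0.01 and -0.05 for apoptosis regulators. Without the sgNS term camera called none of these lists (adjusted p = 0.88, 0.053 and 0.85). With the length and GC trend removed 1 list was called, the large mitochondrial ribosomal subunit (-0.03, 0.024), and the other 10 were not. Medians went to -0.01 for cytosolic ribosomal proteins (0.7), 0.01 for complex I subunits (0.74), -0.01 for ATP synthase (0.28), -0.04 for complex IV (0.36), -0.02 for mRNAs of mitochondrial DNA (0.16) and from -0.05 to -0.02 for import (0.78). They went from 0.07 to 0.04 for RAS-MAPK output (0.15) and from -0.07 to -0.06 for the small mitochondrial ribosomal subunit (0.15), and stayed at 0.07 for apoptosis regulators (0.14) and 0.04 for G2/M genes (0.062), so that the loss of these last 3 calls does not come with a loss of the shift.

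At day 1 the net change involved few genes. MCM4, a subunit of the replicative helicase, fell by 0.3 (SE 0.036, adjusted p = 4.6e-06), at -0.41 in sgZBTB11-1, -0.19 in sgZBTB11-2 and 0.01 in sgNS. KRT15, a keratin, fell by 0.3 (SE 0.047, 0.0011), TXNIP, a thioredoxin-binding protein, by 0.35 (SE 0.064, 0.0059), and GSN, the actin-severing protein gelsolin, by 0.23 (SE 0.042, 0.0052). JUNB (-0.27, SE 0.041, 5e-04) and BHLHE40 (-0.28, SE 0.054, 0.016), both transcription factors, were lower net of sgNS, with DOX changes of 0.23 and 0.2 in sgNS. KIAA1143 (-0.42), HPS6 (-0.48), a subunit of BLOC-2, and ENSG00000269242 (-1.1) were the other decreases among the named genes, and CENPT (0.26) and ENSG00000242588 (0.19) the increases. None of the 37 gene lists was called in camera, where 7 had an unadjusted p under 0.05 and the smallest adjusted p was 0.092. In all 12 genes passed of 16275, 2 higher and 10 lower.

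The day 1 count was 6 without sgNS DMSO replicate 1, and 24 and 21 without sgZBTB11-2 DMSO replicates 1 and 2. Without sgNS DMSO replicate 1 the calls of JUNB (adjusted p = 0.18), BHLHE40 (0.4), GSN (0.18) and TXNIP (0.18) were lost. BHLHE40 was also lost without sgNS DOX replicate 2 (0.13), GSN (0.064) and TXNIP (0.081) without sgNS DMSO replicate 2, and CENPT without sgNS DMSO replicate 2 (0.53), sgNS DOX replicate 1 (0.079) or sgNS DOX replicate 2 (0.083), or in 1 fit of all 70 libraries (0.06). ENSG00000269242 lost its call without sgNS DMSO replicate 1 (0.21) and in the fit of all 70 libraries (0.6), and ENSG00000242588 in 5 of 24 runs (adjusted p up to 0.25). MCM4, KRT15 and KIAA1143 kept theirs without any 1 library, and HPS6 lost its call in 16 of 24 runs. The lists called numbered 1 without sgNS DMSO replicate 1, 9 without sgNS DOX replicate 3, 4 without sgZBTB11-2 DMSO replicate 1, 7 without sgZBTB11-2 DOX replicate 2, 8 with no filter on low counts and 13 without the sgNS term.

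At 5 hr many more genes differed, and the DOX responses of the ZBTB11 guides ran in opposite directions. Cytosolic ribosomal proteins had median DOX changes of -0.17 in sgZBTB11-1, 0.02 in sgZBTB11-2 and -0.29 in sgNS. Of 79, 61 were higher net of sgNS and 18 did not pass (65 higher adjusted over the list alone), for example RPS12 at 0.38 against -0.45 in sgNS (list median 0.22, adjusted p = 1e-25, and 0.14 with an estimated correlation). Of 37 complex I subunits 22 were higher and 1 lower, with NDUFA7 at 0.46 (23 and 2 adjusted over the list alone; median 0.17, 5e-09, and 0.15 with an estimated correlation). Once the length and GC trend was removed the median of the ribosomal proteins was 0.06 (1.5e-05), and that of complex I subunits was 0.04 and not called (0.086). RAS-MAPK output genes were lower, 12 of 24 with 2 higher (13 and 2 adjusted over the list alone; median -0.19, 0.00013, and 0.022 with an estimated correlation), from median DOX changes of 0.07 in sgZBTB11-1, -0.08 in sgZBTB11-2 and 0.16 in sgNS. SPRED1 (-0.8), DUSP6 (-0.42), SPRY1 (-0.38) and ERRFI1 (-0.36), feedback inhibitors of this signalling, were at 0.78, 0.36, 0.36 and 0.28 in sgNS. The share of mitochondrially encoded counts went from 14.1% to 12.1% in sgNS, from 14.1% to 12.3% in sgZBTB11-1 and from 12.6% to 13.3% in sgZBTB11-2, and 9 of 13 mRNAs encoded by mitochondrial DNA were higher net of sgNS, among them MT-CO1 (0.3; also 9 adjusted over the list alone; list 4e-04, and 0.27 with an estimated correlation).

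Among single genes at 5 hr, the nuclear long noncoding RNAs NEAT1 (-0.61, SE 0.045, adjusted p = 8.6e-10) and MALAT1 (-0.57, SE 0.068, 1.7e-05) were lower net of sgNS. They changed by -0.09 and -0.06 in sgZBTB11-1, by -0.15 and -0.05 in sgZBTB11-2, and by 0.49 and 0.52 in sgNS. MIR17HG, host of the miR-17-92 cluster, was lower by a log2 change of -0.66 (SE 0.14, 0.00018). CENPT was higher by 0.74 (SE 0.045, 9.6e-15), FGFRL1, a receptor of fibroblast growth factors, by 0.5 (SE 0.062, 4.1e-08), and NTHL1, a base excision glycosylase, by 0.56 (SE 0.11, 8.1e-05). NTHL1 was at 0.26 (0.068) with the length and GC trend removed. SLC25A40 (-0.64), LAMTOR5-AS1 (-0.55), LRP4 (0.52), ALKBH7 (0.51) and SCAND1 (0.5) also passed, but with the length and GC trend removed ALKBH7 was at 0.19 (0.11) and SCAND1 at 0.2 (0.013). MAGED4 (0.97), which lost its call in 14 of 25 runs, the pseudogenes RPS18P5 and RPL41P2, the latter not with the length and GC trend removed (0.34, 0.12), and the readthrough FMC1-LUC7L2 (-0.97) passed with uncertain reads. In sgNS the largest changes among genes with a mean CPM of at least 5 were CDRT4 (-1.92), TVP23C-CDRT4 (1.41), NPIPA5 (-1.09), SPIN4 (1.07) and CHKB-CPT1B (-1.02), most of them readthroughs or members of gene families.

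The net test at 5 hr called 4683 of 15623 genes, 2301 higher and 2382 lower, with a median size of 0.29 on the log2 scale, and 77 changed by over 1 on that scale. Between the guides 5478 genes differed, 2610 with a higher and 2868 with a lower change in sgZBTB11-2. Of 1845 genes called by DOX in both ZBTB11 guides 1776 went in opposite directions, and across genes the changes had a Pearson r of -0.17 and a Spearman rho of -0.37, where genes are not independent replicates. The 13 lists called, 9 up and 4 down, included G2/M genes (0 higher and 16 lower of 40, 17 lower adjusted over the list alone, 0.00015, and 0.14 with an estimated correlation), S phase genes (4 and 15 of 40 by both adjustments, 0.037, and 0.2 with an estimated correlation) and hypoxia genes (0 and 6 of 20 by both adjustments, 0.037, and 0.27 with an estimated correlation). Only the RAS-MAPK list was kept with an estimated correlation. After removal of the length and GC trend the lists of cytosolic ribosomal proteins, mRNAs of mitochondrial DNA (0.12, 1.5e-05), complex IV (0.09, 0.012) and RAS-MAPK output (-0.15, 1.6e-08) were still called, and the other 9 were not. Among these the median of G2/M genes went only from -0.09 to -0.07 (0.18) and that of complex I assembly factors from 0.13 to 0.09 (0.086), while those of S phase and hypoxia genes went from -0.1 to -0.05 (0.086) and from -0.19 to -0.09 (0.17). The mean of the ZBTB11 guides without the sgNS term gave 10 lists, 1 up and 9 down, with cytosolic ribosomal proteins called down (4.9e-23). On the TPM scale the median gene was at -0.13, and 505 genes were called higher and 3690 lower. There both subunits of the mitochondrial ribosome, complex I assembly factors and complexes II and III, which were called up, stood between -0.08 and -0.03, and all 13 lists kept their direction relative to the median gene. With the length and GC trend removed the net test called 2860 genes and camera 5 lists, and the mean of the ZBTB11 guides without the sgNS term gave 1112 genes, 534 higher and 578 lower.

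At day 5 the list of cytosolic ribosomal proteins and most mitochondrial lists were called down net of sgNS, with the larger part of the shift in sgNS itself. In the large mitochondrial ribosomal subunit, import and expression of mitochondrial DNA, most members did not pass. All 79 cytosolic ribosomal proteins were lower (79 adjusted over the list alone), with a median of -0.47 (adjusted p = 3.2e-259, and 0.0012 with an estimated correlation), from median DOX changes of -0.09 in sgZBTB11-1, -0.17 in sgZBTB11-2 and 0.33 in sgNS. After removal of the length and GC trend this median was -0.22 (4.2e-128), and that of mRNAs of mitochondrial DNA was -0.14 (1.3e-05). RPL30 (-1.08, SE 0.034, 2.6e-30) and RPL7 (-1.08, SE 0.034, 2e-30) were at 0.68 and 0.72 in sgNS. Of 13 mRNAs encoded by mitochondrial DNA 12 were lower, for example MT-CO2 at -0.46 against 0.41 in sgNS (12 adjusted over the list alone; median -0.32, 2.4e-27, and 0.0012 with an estimated correlation), while the share of these counts went from 26.3% to 29.5% in sgNS, from 33.6% to 32.9% in sgZBTB11-1 and from 31.3% to 31.5% in sgZBTB11-2. RAS-MAPK output genes were higher, 10 of 24 with 1 lower (12 higher adjusted over the list alone), led by FOSL1 at 0.76, with a list median of 0.18 (2.4e-06, and 0.0083 with an estimated correlation). Their median DOX changes were 0.02 in sgZBTB11-1, 0.03 in sgZBTB11-2 and -0.12 in sgNS, where the list was called down (0.0073 with an estimated correlation), while it was not called with an estimated correlation in sgZBTB11-1 (0.36) or sgZBTB11-2 (0.082).

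**Figure D2:**
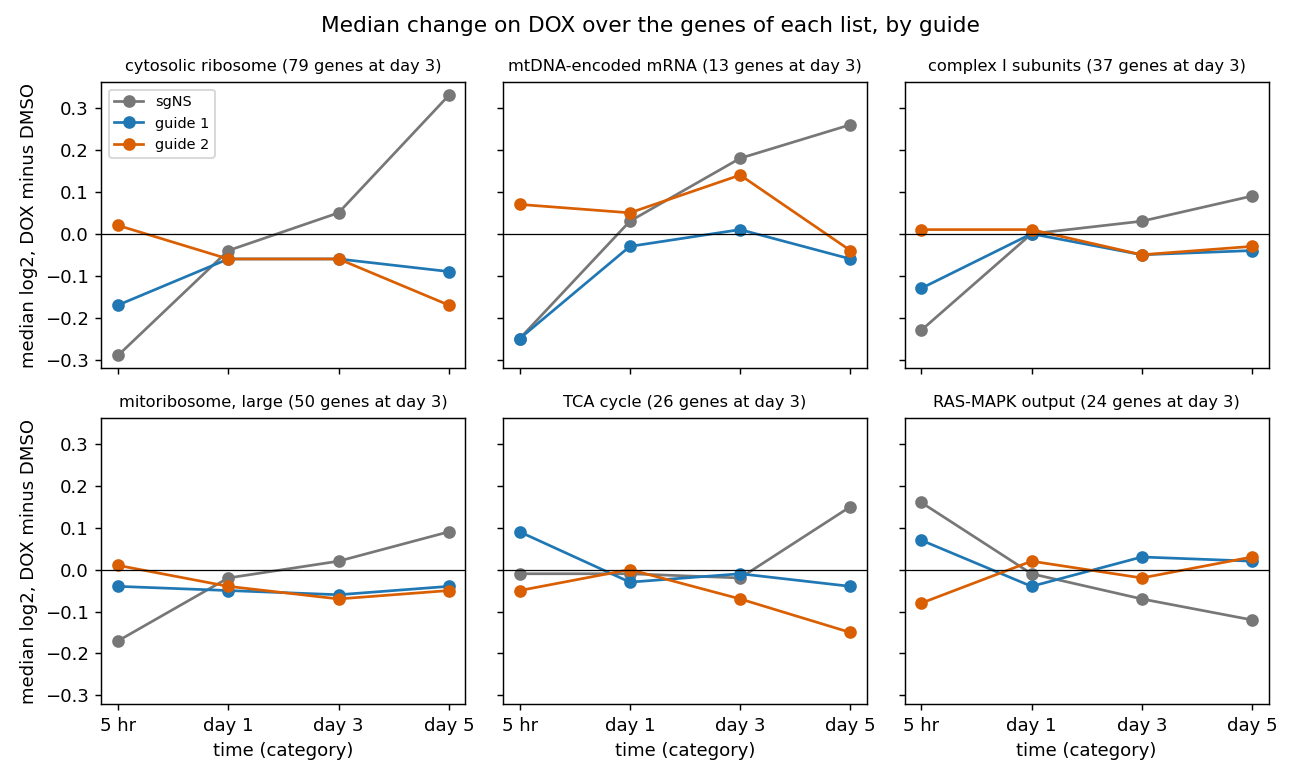
Median log2 change with DOX (vertical axis) of 6 gene lists by time (horizontal axis, categories), with 1 line per guide. At day 5 cytosolic ribosomal proteins stand at 0.33 in sgNS and at -0.09 and -0.17 in sgZBTB11-1 and sgZBTB11-2. On the TPM scale the net medians at day 5 of complex I subunits (0.1), the large mitochondrial ribosomal subunit (0.07) and the TCA cycle (0.01) lie above 0 before the median of all genes (0.19) is subtracted.

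Several other mitochondrial and metabolic lists were called down net of sgNS at day 5, where their genes rose with DOX in sgNS. Median DOX changes of ATP synthase were -0.06 in sgZBTB11-1, -0.11 in sgZBTB11-2 and 0.18 in sgNS. In the same order they were -0.04, -0.15 and 0.15 for the TCA cycle and -0.04, -0.07 and 0.11 for glycolysis. Camera did not call mitochondrial tRNA synthetases (adjusted p = 0.11), serine and one-carbon metabolism (0.28), fatty acid synthesis (0.76) or cholesterol synthesis (0.91). ATP synthase had 13 of 20 lower (14 adjusted over the list alone; 1.9e-18, and 0.012 with an estimated correlation), with ATP5F1E at -0.76. The TCA cycle had 15 of 26 lower (17 lower and 1 higher adjusted over the list alone; 2.1e-07, and 0.0012 with an estimated correlation), with MDH2 at -0.55, and glycolysis 11 of 22 (11 adjusted over the list alone; 1.8e-09, and 0.0015 with an estimated correlation), with PGK1 at -0.51 and TPI1 at -0.48. Complex IV had 19 of 35 lower (23 adjusted over the list alone; 1.6e-10, and 0.013 with an estimated correlation), complexes II and III 13 of 23 (14 lower and 1 higher adjusted over the list alone; 6.7e-08, and 0.012), and the large mitochondrial ribosomal subunit 21 of 50 (24 adjusted over the list alone; 3.5e-08, and 0.026), with MRPL33 at -1.01. Complex I subunits had 17 of 37 lower, with NDUFB3 at -0.71 (also 17 adjusted over the list alone; 3.5e-08), but not with an estimated correlation (adjusted p = 0.088), and their median was 0.06 with the length and GC trend removed. The small subunit (17 of 32, adjusted p = 4.9e-07), import (13 of 38 lower, 1 higher, 7.4e-07), mitochondrial proteostasis (8 of 18 lower, 1 higher, HSPD1 at -0.43, 0.00027), iron-sulfur assembly (6 of 24, BOLA3 at -0.71, 0.0026), complex I assembly (6 of 20, TMEM70 at -0.73, 0.012), fatty acid oxidation (6 of 21, ETFA at -0.53, 0.012) and expression of mitochondrial DNA (12 of 51, SSBP1 at -0.51, 0.016) were called down as well. Adjusted over the list alone, 19, 14, 9, 6, 7, 6 and 14 of their members were lower in that order. Once the length and GC trend was removed ATP synthase went from a median of -0.25 to -0.08 (0.052), complex IV from -0.21 to -0.06 (0.06) and the large mitochondrial ribosomal subunit from -0.14 to -0.02 (0.052), and these calls were lost. Lost as well were those of complex I subunits (0.59), complex I assembly (-0.16 to -0.05, 0.36), iron-sulfur assembly (-0.12 to 0, 0.1), expression of mitochondrial DNA (-0.11 to -0.06, 0.15) and NRF2 targets (-0.05 to -0.03, 0.36). Fatty acid oxidation also lost its call (0.063), but its median went only from -0.14 to -0.12. NRF2 targets (7 of 26 lower, 2 higher, by both adjustments, FTH1 at -0.6; 0.016, and adjusted p = 0.076 with an estimated correlation) and apoptosis regulators (9 of 27 higher, 1 lower, by both adjustments, APAF1 at 0.59; 0.023, and adjusted p = 0.18 with an estimated correlation) lost their calls with an estimated correlation.

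Single decreases at day 5 included TOMM7, a subunit of the outer membrane translocase (-1.34, SE 0.057, adjusted p = 4.4e-15), and SKP1, a subunit of SCF ubiquitin ligases (-1.13, SE 0.055, 3.3e-13). TOMM7 changed by -0.09 in sgZBTB11-1, -0.87 in sgZBTB11-2 and 0.86 in sgNS, and SKP1 by -0.03, -0.76 and 0.73. COX14, a complex IV assembly factor (-1.07), EEF1E1, a component of the tRNA synthetase complex (-1.05), and POLE4, a DNA polymerase epsilon subunit (-1.02), were lower too, as was ENSG00000297649 (-1.16), while reads of the pseudogenes RPL23AP42 (-1.21) and GCSHP5 (-1.06) are uncertain. FOSB, an immediate early transcription factor, was higher by 0.86 (SE 0.036, 3.8e-25), at 0.3 in both ZBTB11 guides and -0.56 in sgNS, and so were ZBTB37 (1.01, SE 0.13, 3e-08) and KLHL15 (0.86, SE 0.1, 1.2e-09).

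The net test at day 5 called 3230 of 16809 genes, 1504 higher and 1726 lower, with a median size of 0.31 on the log2 scale, and 107 changed by over 1 on that scale. In sgNS alone 19 of 37 lists were called, as many as in the net test, where 16 of 19 held with an estimated correlation. On the TPM scale the median gene was at 0.19, and 4487 genes were called higher and 362 lower. There 4 of the 19 called lists had the same sign before this shift was subtracted and the other 15 lay between 0 and 0.14, and relative to the median gene all 19 kept their direction. DESeq2 without independent filtering called 1858 genes, and the mean of the ZBTB11 guides without the sgNS term gave 1237, 400 higher and 837 lower. With the length and GC trend removed 11 lists were called.

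Genes called with DOX in both ZBTB11 guides and net of sgNS, in 1 direction, numbered 33 at 5 hr (18 higher and 15 lower), 5 at day 1 (1 and 4), 16 at day 3 (2 and 14) and 79 at day 5 (19 and 60). This count, and the genes named from it, were chosen after values were seen. The genes of days 3 and 5 shared 9 decreases, where unrelated lists would share 0.052. Besides ZBTB11 these were AGK, MRPL48, MRPL40, of the same mitochondrial subunit as MRPL48, C17orf75, MAN2C1, a cytosolic alpha-mannosidase, DUS1L, a tRNA dihydrouridine synthase, TSEN15, a subunit of the tRNA splicing endonuclease, and ANAPC5, a subunit of the anaphase-promoting complex. Their median DOX changes were -0.26 in sgZBTB11-1, -0.54 in sgZBTB11-2 and 0.06 in sgNS at day 3, and -0.33, -0.57 and 0.05 at day 5. At day 1 the medians were -0.05, -0.07 and -0.06. At 5 hr they were -0.14, 0.06 and -0.16, with 3 of the 9 lower in sgZBTB11-2 than in sgZBTB11-1 and 6 of 9 called as differing between these guides. Net of sgNS at 5 hr MAN2C1 (0.34), DUS1L (0.24) and MRPL40 (0.19) were called higher, and AGK (-0.17) and ZBTB11 lower. Each of the 9 fell more with sgZBTB11-2 on both days, but the edgeR test of that difference passed for 0 of 9 at day 3, where 6 had an unadjusted p under 0.05, and for ZBTB11, MAN2C1 and MRPL40 at day 5. For DUS1L the net change at day 5 was -0.17 on counts and 0.05 on TPM, or -0.14 relative to the median gene.

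**Figure D3:**
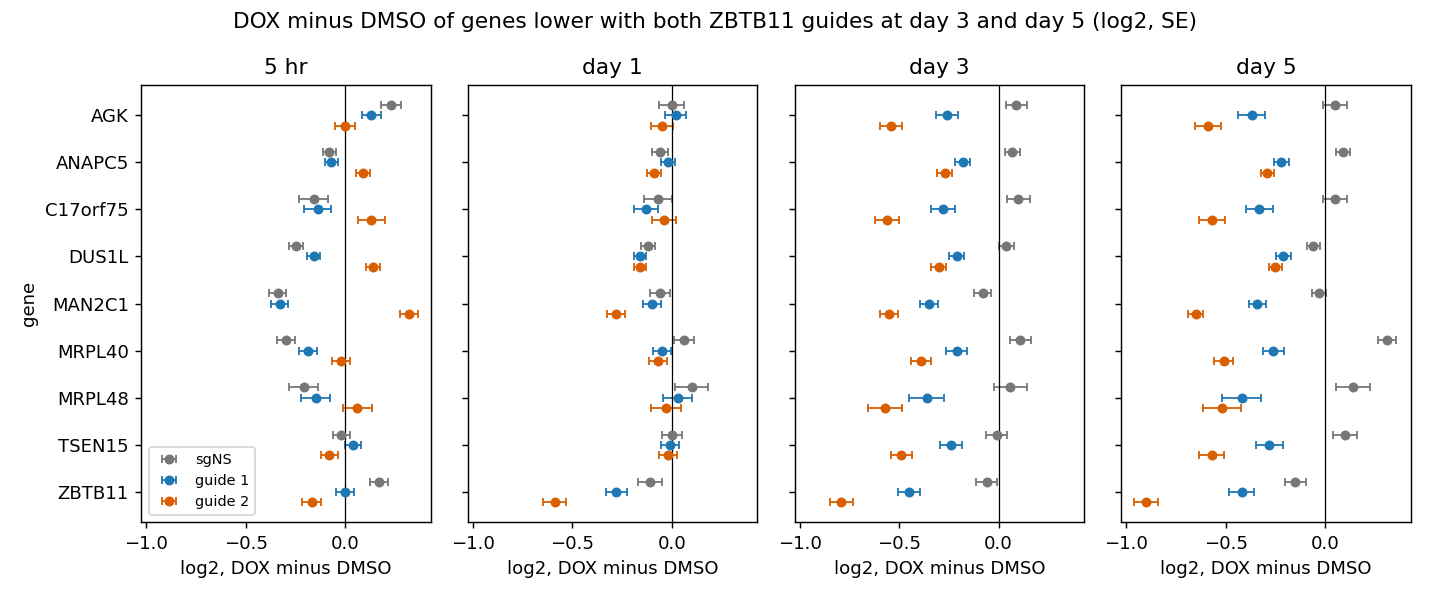
Log2 change with DOX and its SE (horizontal axis) of the 9 genes (vertical axis) that were lower with both ZBTB11 guides and net of sgNS at day 3 and day 5, by guide (colours) and time (panels). AGK stands at -0.26 in sgZBTB11-1, -0.54 in sgZBTB11-2 and 0.09 in sgNS at day 3, and the genes were picked for their values at days 3 and 5.

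COQ3 was among the 16 genes of day 3, but at day 5 its change passed in sgZBTB11-2 (-0.76, adjusted p = 2.1e-07) and net of sgNS (-0.6, SE 0.12, 0.00012) and not in sgZBTB11-1 (-0.32, 0.15). MRPL30 (-0.3, 0.011) and the ATP synthase assembly factor ATPAF1 (-0.28, 0.0027) were others of day 3, and BTG2, an antiproliferative factor, was higher (0.23, 0.0083). At day 5 the increases included the immediate early genes EGR3 (0.8), EGR2 (0.54), NR4A1 (0.6) and FOSB, with EGR2 at 0.44 and 0.55 in the ZBTB11 guides and -0.04 in sgNS, and the decreases included ETV4 (-0.36), a transcription factor of the ETS family. TXNIP and KRT15 were lower at both day 1 and day 5, where unrelated lists would share 0.015 decreases. Single libraries moved these counts: at 5 hr to 16 and 21 without sgZBTB11-2 DMSO replicate 2 and DOX replicate 2. At day 1 they moved to 3 and 2 without sgNS DMSO replicates 1 and 2, and to 8 without sgZBTB11-2 DMSO replicate 1. At day 3 they moved to 25 without sgNS DMSO replicate 1, to 10 without sgNS DOX replicate 3, to 10 without either of sgZBTB11-1 DMSO replicates 2 and 3, and to 8 without sgZBTB11-1 DOX replicate 3. At day 5 they moved to 21 and 35 without sgZBTB11-1 DMSO replicates 1 and 2, and to 43 and 45 without its DOX replicates 1 and 3. In DESeq2 without independent filtering they were 16 at 5 hr, 8 at day 3 and 47 at day 5.

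The guides were also compared gene by gene. Calls with DOX shared by sgZBTB11-1 and sgZBTB11-2, which share no library, exceeded n1 × n2 / N at days 1, 3 and 5 and fell short of it at 5 hr. Decreases shared numbered 36 at 5 hr against 209 for unrelated lists, 257 against 23.1 at day 1, 40 against 0.806 at day 3 and 68 against 7.8 at day 5. Among genes with a mean CPM of at least 5, Pearson's r across genes was -0.55 at 5 hr, 0.49 at day 1, 0.25 at day 3 and 0.19 at day 5. Against sgNS, r was 0.76, 0.39, 0.01 and -0.18 for sgZBTB11-1 and -0.61, 0.44, 0.19 and -0.39 for sgZBTB11-2 at these times. The change of a gene with DOX differed between these guides past the threshold for 10 genes at day 1, 3 at day 3 and 434 at day 5. The count at day 1 was 139 without sgZBTB11-2 DMSO replicate 1, 18, 6 and 6 without sgZBTB11-2 DOX replicates 1, 2 and 3, 6 and 1 without sgZBTB11-1 DMSO replicates 1 and 2, and 3 and 4 without sgZBTB11-1 DOX replicates 1 and 2. The count at day 5 was 245 without sgZBTB11-1 DMSO replicate 1.

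Genes next to ZBTB11 were examined because repression by dCas9-KRAB can reach neighbouring promoters. ZBTB11-AS1, which overlaps the start of ZBTB11 (chromosome 3, 101676430 to 101679217), did not pass net of sgNS at any time (adjusted p = 0.64, 0.94, 0.65 and 0.89), and its reads cannot be told apart from those of ZBTB11 without the strand setting. No other neighbour was called at day 1. NFKBIZ was higher net of sgNS at day 3 (0.47, 0.0083) and day 5 (0.46, 1.7e-05), and CEP97 was higher (0.41, 0.034) and RPL24 (-0.39, 8.8e-14) and TRMT10C (-0.32, 0.0098) were lower at day 5. At 5 hr PCNP (-0.25), SENP7 (-0.49) and CEP97 (-0.46) were lower and RPL24 was higher (0.17). RPL24 is itself a cytosolic ribosomal protein, and its changes were no larger than the medians of that list. Those medians were -0.47 at day 5, with 79 of 79 lower, and 0.22 at 5 hr, with 61 of 79 higher. Its calls are thus not particular to a neighbour of ZBTB11. RPL24 at 5 hr lost its call in 13 of 25 runs (0.05 to 0.25, adjusted p up to 0.24). SENP7 lost it in 4 of 25, among them without sgNS DOX replicate 1 (0.065). With the length and GC trend removed PCNP (-0.05, 0.44), SENP7 (-0.2, 0.41) and CEP97 (-0.21, 0.28) were not called at 5 hr. CEP97 at day 5 lost its call in 11 of 24 runs (0.26 to 0.49, adjusted p up to 0.31), and RPL24 at day 5 kept its call at -0.42 to -0.09, with -0.09 once the length and GC trend was removed. The list of neighbours was not called at any time (0.4, 0.94, 0.053 and 0.91). NFKBIZ at day 3 lost its call without sgNS DMSO replicate 3 (0.075), and TRMT10C at day 5 without sgNS DMSO replicate 1 (0.057), and both lost it in DESeq2 without independent filtering (0.058 and 0.093).

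Net changes were compared between neighbouring times in 1 fit of 18061 genes. They differed for 3083 genes between 5 hr and day 1 (1510 with a higher and 1573 with a lower change at day 1), for 31 between days 1 and 3 (21 and 10) and for 1084 between days 3 and 5 (419 and 665). Without replicate 1, 2 or 3 of every group the counts were 1729, 1809 and 1763 for the first of these and 4, 7 and 1 for the second, and 494 and 656 without replicates 1 and 3 for the last.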

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

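The tests on transcript length and GC content at 5 hr and day 5, on exchanged DMSO and DOX labels, on the overlap of unrelated lists, on the lower ZBTB11 and on reads shared by overlapping genes were chosen only after the results were seen.

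Tests of the difference between times or between guides singled out the following results. Net changes differed between 5 hr and day 1 for 3083 genes, between days 1 and 3 for 31 and between days 3 and 5 for 1084. DOX changes differed between the ZBTB11 guides for 5478 genes at 5 hr, 10 at day 1, 3 at day 3 and 434 at day 5. ZBTB11 itself fell more with sgZBTB11-2 than with sgZBTB11-1, by a difference of -0.17 at 5 hr and -0.48 at day 5. At 5 hr the 5478 genes, of 15623 tested, had a median size of 0.37, so the smaller difference of ZBTB11 was not particular to it. The differences at day 1 (-0.32, SE 0.078) and day 3 (-0.33, SE 0.08) were larger in size than at 5 hr. They did not pass after adjustment over all genes tested, which does not show that the guides were alike at these times.

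Many genes differed net of sgNS at 5 hr (4683) and day 5 (3230), with the larger part of the ribosomal shift in sgNS itself. With every library thinned to the lowest total of its time the counts were 4278 and 2792, and in 3 of 3 guides at each of these times every DOX library was above every DMSO library for CENPT, which argues against a difference in depth and against DMSO and DOX labels exchanged for a guide. With the trend with transcript length and GC content removed, 2860 and 3018 genes passed, which argues against this trend as the whole cause. Among genes with a mean CPM of at least 5, however, the trend took up 42.5% of the variance of the net change at 5 hr and 22.5% at day 5. A difference in culture or handling between the DMSO and DOX dishes of a guide may still be part of the cause, and nothing in the labels records it. At 5 hr, among genes with a mean CPM of at least 5, the responses of the ZBTB11 guides were opposite (Pearson's r -0.55). The response of sgZBTB11-1, where ZBTB11 itself stood at 0, followed that of sgNS (r 0.76). DOX changed 6395 genes in sgNS, which does not target ZBTB11. These values argue against a response to ZBTB11 as the main cause at 5 hr. At day 5 DOX changed 2915 genes in sgNS, 191 in sgZBTB11-1 and 1513 in sgZBTB11-2. There a response to ZBTB11 cannot be told apart from a difference in culture or handling.

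The other pattern weighed is that of the genes lower with both ZBTB11 guides and net of sgNS at day 3 and again at day 5, which numbered 9 with ZBTB11 among them. Unrelated lists would share 0.052 if every gene were equally likely to be called, and such an overlap does not account for them. At day 3, 8 of the 9 kept all 3 calls once the length and GC trend was removed, so this trend does not account for most of them there. Their calls at day 5 were not checked in this way. Besides ZBTB11, 8 of 8 genes fell more with sgZBTB11-2, which lowered ZBTB11 more, at both days, but so did 39 of the 51 other genes with the same 3 calls at day 5 and 3 of 5 at day 3. An effect of lower ZBTB11 on these genes therefore cannot be told apart from a generally larger response in sgZBTB11-2 cells, and it stays open as a hypothesis.

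The last pattern weighed is the rise of CENPT and the fall of THAP11 with DOX in all 3 guides. THAP11 lost 8.64% of the counts-per-million that CENPT gained in sgNS at day 1, so reads shared between the overlapping genes do not account for most of the rise of CENPT. For the fall of THAP11 this test cannot decide. Its change of -13.4 CPM is small beside the gain of 155 CPM for CENPT, so shared reads could still account for it. Of 20 other tested genes within 250 kb of CENPT, 0 were called in all 3 guides in edgeR at day 1, which argues against a change of the whole chromosome neighbourhood. A response to DOX, or to the induced dCas9-KRAB whatever its guide, may be the source, and the design holds no cells that separate these. No biological explanation was tested for it.

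Other splits of the libraries into DMSO and DOX within guides were counted, the real one included. Of 50 splits, a count of net changes as large as the real one came from 2 at 5 hr (real 4683, highest other 4838), 1 at day 1 (12 and 1), 1 at day 3 (82 and 77) and 1 at day 5 (3230 and 885). Each share is under 0.05. These splits exchange DMSO and DOX within guides, so most of them place the DOX change of a guide in the spread between libraries. A small share thus speaks to a change with DOX in some guide, and cannot decide whether the net counts exceed chance, also at days 1 and 5. At 5 hr another split exceeded the real count, and at day 3 another came close to it, so chance is not excluded at these times either. The highest other splits at 5 hr and day 5 exchanged labels in both ZBTB11 guides and 0 in sgNS, and that at day 3 exchanged 4 of the 6 labels of sgNS and 0 in the ZBTB11 guides. The split with 4838 genes at 5 hr points to a structure of the samples in which the sgNS libraries part from each other by treatment. For differences between guides, 1 of 50 splits was as large at 5 hr (5478 and 23) and at day 5 (434 and 63), with the same limit. It was 3 of 50 at day 1 (10 and 156) and day 3 (3 and 19), which does not exclude chance. The highest other splits for these 2 days called several times the real count and point to a structure of the samples as well. For gene lists, 2 of 50 splits were as large at 5 hr (13 and 13), a share under 0.05, but another split called as many lists as the real one. The shares of 6 of 50 at day 3 (11 and 19) and 3 of 50 at day 5 (19 and 22) do not exclude chance. At day 1 the real count is 0 (highest other 11), so that 50 of 50 splits are as large whatever the data and the count of splits says nothing. The median number of lists called by the other splits was 3, 3, 4 and 3 at these times.

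For differences between times, 1 of 25 splits was as large for day 1 against 5 hr (3083 and 1804), day 3 against day 1 (31 and 1) and day 5 against day 3 (1084 and 195). These splits exchange labels in the same way, so this share speaks to a change with DOX and does not exclude chance for the differences between times. A set of 25 splits can give no smaller share. Within a guide only 10 splits exist, too few for a share under 0.05. For sgZBTB11-1 the real count and the highest other were 5130 and 0 at 5 hr, 787 and 1 at day 1, and 122 and 1 at day 3. For sgZBTB11-2 they were 2659 and 1 at 5 hr, 1282 and 1 at day 1, 195 and 2 at day 3, and 1513 and 3 at day 5, and for sgNS 6395 and 6 at 5 hr, 146 and 2 at day 3, and 2915 and 1 at day 5. In each of these comparisons 1 split, the real one, gave a count as large.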

How the results depend on the processing

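The length and GC trend, the fit without the sgNS term, DESeq2 without independent filtering and the count of genes called with both ZBTB11 guides and net of sgNS were chosen after seeing the data. Among counts, correlations and the ZBTB11 values, 443 kept their side of the threshold or stayed near the main value, and 124 counts or correlations moved further. Near meant within 1.5 times for a count, and within the SD over left-out libraries for a correlation. The ZBTB11 values of this tally were compared with TPM alone, where 8 lost and 1 gained a call. None of the called values in this tally reversed. On counts in edgeR the net call of ZBTB11 at 5 hr was lost with the length and GC trend removed (-0.04, adjusted p = 0.71). Its net change at day 1 passed in some count settings, as given above. A count within 1.5 times can hide a change of direction: without the sgNS term 10 lists were called at 5 hr, 1 up and 9 down, against 9 up and 4 down. Values that did not pass changed sign 31 times, among them ZBTB11 with DMSO in sgZBTB11-1 against sgNS at day 1 (-0.09, and 0.05 on TPM). RLE scaling and the fit of all 70 libraries moved no count by over 1.5 times. For named genes RLE scaling moved 0 of 123 values across the threshold, DESeq2 ended 2 calls and gave no adjusted p at day 3 for 25, of which edgeR called 18, and DESeq2 without independent filtering ended 17, the fit of all 70 libraries 7, the length and GC trend 16, no filter 1 and left-out libraries 181 against 1969 values that kept their side and 8 that gained a call, with 0 called values reversed on counts. Where a value moved, the cause was not tested, except that DESeq2 without independent filtering adjusts over more genes. At the depth and number of libraries of day 3, 40% of genes changed by 0.25 were called in simulated data. The changed genes had a mean CPM of at least 5, and depth was not varied.

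On log2(TPM + 1) in limma, ZBTB11 in sgZBTB11-2 with DMSO against sgNS was 0.24 at 5 hr (adjusted p = 0.015), -0.06 at day 1 (0.7) and -0.27 at day 3 (0.13). With DOX in sgZBTB11-1 it was -0.16 at day 1 (0.39), -0.42 at day 3 (0.053) and -0.29 at day 5 (0.22), in sgZBTB11-2 -0.16 at 5 hr (0.19), and net of sgNS -0.43 at day 3 (0.089) and -0.23 at day 5 (0.069). Net changes of named genes, not tested there, had the opposite sign on TPM for 3 of 41 at 5 hr, 3 of 31 at day 1, 0 of 35 at day 3 and 1 of 35 at day 5, and for 1, 2, 0 and 0 relative to the median gene. Of those called on counts this was DUS1L at day 5 alone (-0.17 on counts, 0.05 on TPM). The net test there called 3 genes at day 1, 22 at day 3 and 4849 at day 5 (4487 higher and 362 lower, against 1504 and 1726 on counts). Among genes with a mean CPM of at least 5, agreement between guides was -0.55, 0.49, 0.25 and 0.19, against -0.17, 0.04, 0.08 and 0.15 for all genes, at 5 hr and days 1, 3 and 5.

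With an estimated correlation 1 list was called at 5 hr and 0 at day 3. With the length and GC trend removed, lists numbered 5 at 5 hr, 1 at day 3 and 11 at day 5, net changes 2860 at 5 hr and 21 at day 1, DOX changes 222 in sgNS at day 3 and 793 and 307 in sgZBTB11-2 at days 1 and 3, differences between guides 35 at day 1 and 8 at day 3, and genes called with both guides and net 8 at day 1. With no filter on low counts, lists numbered 8 at day 1, net changes 27 at day 1 and 195 at day 3, DOX changes in sgNS 262 at day 3, differences between guides 96 at day 1 and 35 at day 3, and genes called with both guides and net 8 at day 1. Without the sgNS term the net test became 1112, 2249, 420 and 1237 at the 4 times, and lists numbered 13 at day 1 and 21 at day 3. DESeq2 gave 53 differences between guides at day 1. DESeq2 without independent filtering gave 200 and 1636 DOX changes in sgNS at days 1 and 5, 441, 78 and 85 in sgZBTB11-1 at days 1, 3 and 5, and 1656, 633 and 820 in sgZBTB11-2 at 5 hr and days 1 and 5. It gave 45 and 1858 net changes at days 3 and 5, 220 differences between guides at day 5, and 16, 8 and 47 genes called with both guides and net at 5 hr and days 3 and 5.

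With the replicate number as a block the net test called 4837, 12, 84 and 3219 genes at the 4 times, and it moved no count by over 1.5 times, but it ended 3 calls of named genes: CEP97 at day 5 (0.05), HPS6 at day 1 (0.053) and RPLP0P9 at day 3 (0.077). Over all times no pairing by these numbers was seen. Deviations from group means had a mean r of 0 over 170 pairs with the same number, 22 of them above 0.1, and of 0 over 340 pairs with different numbers, 46 of them above 0.1. At 5 hr alone the mean r was 0.03 over 45 pairs with the same number and -0.02 over 90 with different numbers.

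Leaving out each library in turn gave the following lowest and highest values at 5 hr and days 1, 3 and 5. Net changes numbered 4045 to 4704, 6 to 24, 29 to 262 and 2758 to 3232, and lists 11 to 15, 0 to 9, 9 to 13 and 19 to 19. DOX changes in sgNS numbered 5524 to 6019, 103 to 323, 40 to 278 and 2229 to 2733, in sgZBTB11-1 4288 to 4747, 420 to 543, 44 to 122 and 27 to 140, and in sgZBTB11-2 1797 to 2624, 599 to 1965, 109 to 168 and 1022 to 1328. Differences between guides numbered 4987 to 5377, 1 to 139, 2 to 4 and 245 to 514, and genes called with both guides and net 16 to 37, 2 to 8, 8 to 25 and 21 to 111. Without each replicate number, differences between times numbered 1729 to 1809, 1 to 7 and 494 to 822.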

Other observations

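The tests of lists within each guide with an estimated correlation were chosen after the results were seen. Genes of ribosome biogenesis were called down as a list at day 1 in every guide, sgNS included. The 39 tested genes of this list, which make and assemble ribosomes in the nucleolus, had median log2 changes of -0.14 in sgZBTB11-1, -0.11 in sgZBTB11-2 and -0.12 in sgNS (camera, adjusted p = 3.3e-21, 2.8e-13 and 6.7e-18, and 0.0023, 0.012 and 0.0066 with an estimated correlation). In the same order 38, 38 and 37 of the 39 had a change below 0, and 19, 16 and 6 passed the threshold as lower with 0 higher (29, 20 and 22 lower adjusted over the list alone). RRP9, a component of the U3 snoRNP, fell by 0.27 in sgZBTB11-1 (0.0049) and 0.33 in sgZBTB11-2 (0.00038) and was at -0.1 in sgNS (0.53), while DDX21, a nucleolar RNA helicase, fell by 0.25 in sgNS (2.1e-05); both genes were chosen after their values were seen. The epithelial list, with 10 tested genes and medians of -0.17, -0.15 and -0.05, was called down in each guide as well (1.1e-06, 6.7e-05 and 0.00047, and 0.0023, 0.012 and 0.017 with an estimated correlation). S phase genes were also called down in each guide (8e-07, 0.0044 and 3.5e-05, and 0.0074, 0.19 and 0.024 with an estimated correlation), as was the small mitochondrial ribosomal subunit (4.1e-08, 0.0025 and 0.0033, and 0.011, 0.19 and 0.13 with an estimated correlation). Cytosolic ribosomal proteins (3.5e-10, 1.3e-07 and 3.5e-05) and glycolysis (0.002, 0.0044 and 0.00055) were called down in each guide, and in none with an estimated correlation (from 0.37 to 0.7 and from 0.11 to 0.19). DOX is known to inhibit mitochondrial ribosomes, and its effect on these cells without dCas9-KRAB was not analysed here.

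The share of counts from mitochondrial DNA rose from 11% ± 1 at day 1 (SD, n = 17) to 30.7% ± 2.5 at day 5 (n = 17) over all guides and treatments, and was not compared by a test. With DMSO, ZBTB11 guides also differed from sgNS in many genes: 5005 for sgZBTB11-1 at 5 hr, 3453 at day 1, 3272 at day 3 and 3666 at day 5, and 5036, 1743, 553 and 3029 for sgZBTB11-2. Of the marker lists of other cell types, fibroblast markers had 4 tested genes of 11, immune markers 2 of 12 and endothelial markers 1 of 8, too few for a list test.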
